A study of Oryza sativa with 3 samples.

How the data were processed

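Leaf RNA from 3 rice samples was measured on Affymetrix rice GeneChip arrays, 1 array per sample. The groups came from the genotype given in the labels: 1 control sample of the cultivar Guichao2 and 2 samples of OsEBS-transgenic Guichao2, the lines B10201 (replicate 1) and B10301 (replicate 2). Per the labels, each sample came from the leaves of 10 plants aged 6 weeks, grown untreated in a greenhouse with 14 h of light and 10 h of dark at 28 °C. The labels give the 2 transgenic samples as separate lines and say nothing of further independent plantings, so p-values measured only the spread between these samples, which may in part be technical. The number of arrays limited the precision of every value.

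Per the labels' protocols, total RNA was labelled with biotin by 3' in vitro transcription. The deposited table holds log2 signals that the authors made with MAS5, per the submitters' processing notes; no version, detection call or further step is given in the sources used here. The deposited log2 values fell as low as 0, a linear signal of 1. After conversion to linear signal, the trimmed means of the 3 arrays were 460.0, 459.2 and 460.0 over the probe sets analysed, and the median log2 signals were 5.35 (control), 5.50 (B10201) and 5.49 (B10301). No further normalization was applied for the values reported.

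The table was checked for misplaced values only after comparisons of all values as deposited had set B10301 apart from the other arrays. A Viterbi path over offsets of up to 3 places between each pair of columns found no stretch out of step between the control and B10201. In the B10301 column it found 2 stretches, of 6717 and 988 consecutive probe sets, whose values stood 1 place away from their own probe set. Those stretches, with a margin of 20 probe sets at each end, were left out: 7785 of the 57194 probe sets (13.6%), with 3762 genes inside the stretches. The remaining 49409 were analysed. This departed from the plan made before the data were examined, which used every probe set; results from all values as deposited, and with the B10301 values of the stretches moved back by 1 place, are given as alternatives in the closing section.

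Signals were raised to a floor at the median of all signals, 5.45 on the log2 scale (43.8 in linear signal). Probe sets whose mean over the 3 arrays was above that floor were kept, 22772 of 49409 (46.1%). A probe set at the floor on 1 side of a comparison gives only a bound, written as at least so many fold. Log2 ratios were each line's log2 signal minus that of the control array. With 1 control array, counts of probe sets at least 2-fold from the control carry no test, and a difference was required in both lines. limma 3.58.1 in R 4.3.3 was fitted to all 3 arrays with an intensity trend, 1 residual degree of freedom from the 2 lines and a two-sided Benjamini-Hochberg threshold of 0.05, so the control was assumed to vary like the lines. The words higher and lower therefore describe measured values, not calls. All other steps were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and the plots with matplotlib 3.10.9.

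Gene identities came from the platform annotation, matched by gene identifier to the gene table of assembly ASM3414082v1. Of the 49409 probe sets, 18013 were listed with 1 gene, 81 with several and 31315 with none; probe sets with several or no gene were left unnamed. The 14537 genes listed were all found in the gene table, and 11900 had a probe set above the floor. A gene with several probe sets was represented by the one with the highest mean. Suffixes x_at and s_at mark probe sets that may cross-hybridise; they made up 22.2% of those kept. The assembly was used for names and for the order of genes along chromosomes only.

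The rule for named genes was fixed before the data were examined: per direction, the 12 genes with the largest smaller-of-2-lines ratio among probe sets past the limma threshold, filled up from those at least 2-fold in both lines; up to 3 genes per list; OsEBS or, failing a match, Hsp70 genes; and the 5 genes per direction that differed most between the lines. The Hsp70 genes meant in that rule were those of chromosome 5. Most genes ranked by the rule carry only a locus number, so the same ranking was repeated after the data were seen over genes with a readable symbol (1684 of 11900). The 30 gene lists fixed before the data were examined were written to match descriptions, which the annotation used here does not hold: 27 could not be measured, those of WRKY transcription factors and diterpene phytoalexin synthesis had at least 3 measured members, and the Hsp70 pattern matched 7 measured genes of which 1 is an Hsp70 gene. After the annotation was seen and before any ratio was computed, 44 lists were written as patterns of gene symbols; 41 had at least 3 measured members. A list's median log2 ratio was set against 10000 random lists of the same size matched on mean signal, and a list stood apart when its percentile was under 2.5 or over 97.5 in both lines. If the members of a list varied independently, about 2.05 of 41 lists would lie beyond those bounds in a single line. Members of a list may vary together, so the number without any effect of the transgene may be higher.

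The ratio of each line to the same control array shares that array's error. An SD over the 2 lines leaves that error out and measures only how closely the lines match. Counts, correlation and covariance were therefore set beside 100 simulations of unchanged lines with 1 common control, with noise of the size seen between the lines at the same signal. Simulated data with known changes tested both procedures on 22772 probe sets: requiring 2-fold in both lines recovered 31.3% of 67 probe sets changed 2-fold, and all of the 67 changed 4-fold and 66 changed 8-fold, while limma called 0 of the 67, 67 and 66, with unadjusted p under 0.05 for 50, 66 and 66 of them. Alternatives planned before the data were examined were quantile normalization, centring of each array on its median, floors at the 25th and 75th percentile or none, leaving out x_at and s_at probe sets, 1 probe set per gene, thresholds of 1.5-fold and 3-fold, each line alone, limma without the trend, with robust moderation or at a threshold of 0.1, and the mean of a gene's probe sets. Chosen after seeing the data were the treatments of the displaced stretches, limma on values not raised to the floor, the mean of a gene's probe sets for named genes, the ribosomal list without RPP symbols, and the tests of gene order other than that of neighbouring genes in B10301, which was written before its result was seen.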

Results

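The data comprised log2 expression signals in leaves of 6-week-old rice plants, with 1 array of control Guichao2, an indica cultivar, and 1 array for each of 2 lines of Guichao2 carrying an OsEBS transgene, B10201 and B10301. OsEBS is known as a rice gene linked to biomass and spikelet number whose product is related to Hsp70 chaperones. The design addresses which transcripts differ between leaves of the transgenic lines and those of the control cultivar. The arrays had similar overall signal: 48.7% of the control's probe sets lay above the common floor, against 50.8% for B10201 and 50.5% for B10301.

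In 2 stretches of the value table the B10301 signals stood 1 place away from their probe sets. Across the probe sets of the longer stretch, the correlation of B10301 with the mean of the other arrays was 0.397 as deposited and 0.939 after moving the values by 1 place; in the shorter stretch it was 0.051 and 0.823. The control and B10201 correlated at 0.917 and 0.787 in the same stretches. Neighbouring probe sets for the same transcript gave an internal check: inside the stretches, over 384 pairs, they correlated at 0.705 in the control, 0.722 in B10201 and 0.393 in B10301, and at 0.71 in B10301 once moved. Outside, over 3684 pairs, the values were 0.677, 0.673 and 0.664. These are correlations across probe sets, which are not independent replicates. The stretches were left out of all comparisons below.

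Leaves of both transgenic lines had higher signals than the control for cellulose synthase genes and lower signals for chitinase genes. Cellulose synthases and related enzymes, which build the glucan chains of the cell wall, were higher in both lines, with CESA1 at a mean log2 ratio of 1.17 ± 0.21 (SD, n = 2 lines), CESA4 at 1.16 ± 0.18 and CSLC2, a synthase of the xyloglucan backbone, at 1.13 ± 0.10. The beta-expansin EXPB2, of a family that loosens cell walls, was at the floor in the control, and its log2 ratios of 3.50 in B10201 and 4.65 in B10301 are lower bounds, at least 11.3-fold in the former. Expansins as a list lay within the random lists (percentiles 88.9 and 77.8). Chitinases and pathogenesis-related proteins, which act against fungal cell walls and microbes, were lower. Among them were PBZ1, a probenazole-induced defence protein, at -1.56 ± 0.26, and the chitinase Cht2 at -1.22 ± 0.09. The probe sets of Cht2 disagreed in sign and averaged -0.73. As single genes, the lipoxygenase LOX9, of a family that oxidises fatty acids on the way to jasmonate and other oxylipins, was lower at -2.26 ± 0.30, although the jasmonate list that holds it had medians of 0.26 and 0.16, and CYP71P1, the tryptamine 5-hydroxylase of serotonin synthesis, at -1.96 ± 0.11.

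Of 22772 probe sets, 1243 were at least 2-fold from the control in both lines, 546 higher and 697 lower, while 13 went opposite ways. The balance of directions turned with centred arrays (632 higher, 593 lower), a floor at the 25th percentile (3068 and 2308) and no floor (5601 and 4034). With 1 probe set per gene the count was 559 of 11900 genes, 245 higher and 314 lower, and among genes with a readable symbol 24 were higher and 52 lower of 1684. limma called 0 probe sets after Benjamini-Hochberg adjustment (lowest adjusted p = 0.0709), with 3837 at an unadjusted p under 0.05. The number of limma calls depended on the setting: 0 with quantile normalization, with floors at the 25th or 75th percentile, without x_at and s_at probe sets, without the trend, as deposited or with the displaced values moved, but 22 with centred arrays (20 higher, 2 lower), 119 without a floor (74 higher, 45 lower), 85 with kept values not raised to the floor (65 higher, 20 lower), 45 with robust moderation (35 higher, 10 lower), 10 at a threshold of 0.1 (all higher) and 2 with 1 probe set per gene (both higher). In simulated data of the same size limma called 0 of 66 probe sets changed 8-fold, so a count of 0 could not show an absence of change.

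The largest differences belonged to genes known only by locus number, whose function is not given in the annotation used here. LOC4352807 was 145-fold higher in B10201 and 138-fold higher in B10301, and LOC9266439, measured by an s_at probe set, 97.6-fold and 100.1-fold (mean log2 ratio 4.18 with its probe sets averaged). These were the 2 genes called by limma with 1 probe set per gene, at adjusted p = 0.022 and 0.026. LOC4339148, with a control signal (5.47) next to the floor (5.45), was higher by log2 ratios of 6.03 and 5.84, best read as bounds. LOC4342242, at the floor in the control, was at least 58.5-fold and 61.7-fold higher, and LOC4342234 at least 28.2-fold and 31.8-fold (mean log2 ratio 3.87 with its probe sets averaged). LOC4352102 went the other way, from well above the floor in the control to the floor in both lines, at least 100.3-fold lower, as did LOC9270774 (x_at), at least 43.2-fold lower. LOC4352036 was lower by at least 60.7-fold in B10301, where it was at the floor, with a log2 ratio of -4.14 in B10201.

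The other genes named by the same ranking were LOC4349948 (log2 ratios 4.51 and 4.97), LOC4339438, LOC4339714, LOC9268076, LOC4340325, LOC4350133 and LOC4339505 (mean 3.74 ± 0.20) on the higher side, and LOC4328867 (s_at), LOC4333968, LOC9266242 (-3.25 and -3.81), LOC4350650, LOC4334934 (s_at), LOC4334549, LOC4351029, LOC4339705 and LOC4347880 on the lower side. Of these, LOC4339438, LOC4339714, LOC9268076, LOC4340325 and LOC4350133 were at the floor in the control, and LOC4328867, LOC4333968 and LOC4351029 at the floor in both lines.

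**Figure D1:**
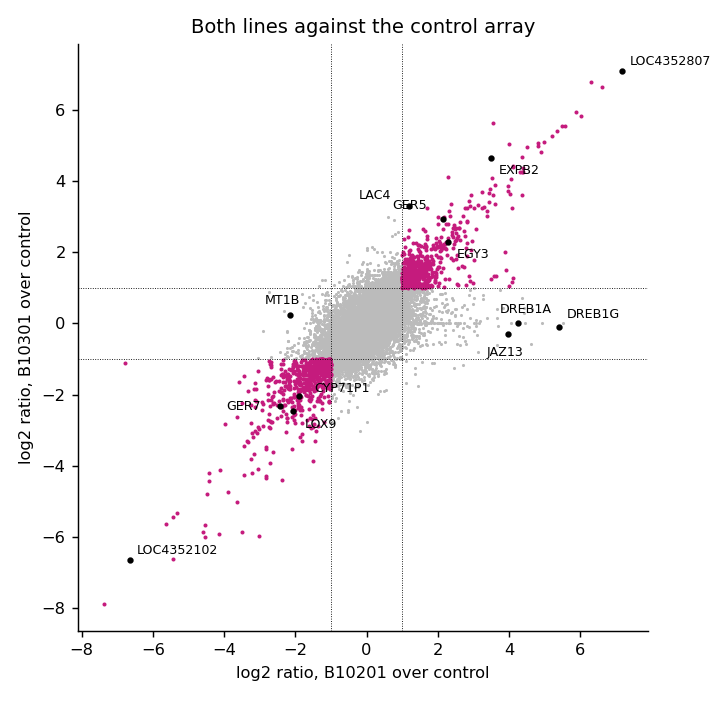
Log2 ratio over the control of each of 22772 probe sets in B10201 (horizontal) and B10301 (vertical), with dotted lines at 2-fold; points at least 2-fold the same way in both lines are magenta, and black points are named genes. The 546 higher and 697 lower probe sets lie along the diagonal, up to LOC4352807 at 7.18 and 7.10, while DREB1G, DREB1A and JAZ13 lie to the right with B10301 near 0.

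Among genes with a readable symbol, those higher in both lines after EXPB2 were EGY3, a member of a family of chloroplast membrane proteases, with a mean log2 ratio of 2.29 ± 0.01 (SD, n = 2 lines), and GER5, a symbol used for a germin-like protein, at 2.53 ± 0.56. OsTIP4;2, a tonoplast aquaporin measured by an x_at probe set, was at 1.79 ± 0.15, and OsUGE-1, a UDP-glucose 4-epimerase that supplies UDP-galactose for wall polymers, at 1.64 ± 0.04. SPL7, OsTBL6 (s_at), the beta-glucosidase BGLU32 (s_at) and the potassium transporter HAK22 (x_at) followed with means of 1.57, 1.66, 1.48 and 1.52; the other probe set of HAK22 disagreed in sign, and the mean of both was 0.43. AS2 (x_at), the growth-regulating factor GRF3 and the homeodomain gene Hox19 (x_at) were at the floor in the control, and their log2 ratios, at least 1.75, 1.31 and 1.28 in the line with the lower value, are bounds.

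On the lower side stood GER7, a second germin-like symbol, at -2.37 ± 0.07, AT5 at -2.65 ± 0.65, a gene listed as peroxidase at -2.13 ± 0.45 and AtUREG at -2.19 ± 0.73. CYP71Z7, a cytochrome P450 of diterpenoid phytoalexin synthesis, was at -1.93 ± 0.60, the calmodulin-like CML9 at -1.67 ± 0.09, the protein phosphatase OsPP2C59 at -1.79 ± 0.36 and LOGL9, of the family that releases active cytokinin, at -1.70 ± 0.24. FAS2 and the kinesin KIN7L reached the floor in B10301. No gene in these paragraphs passed the limma threshold over all probe sets; adjusted p ranged upwards from 0.0709 for LOC4352807.

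**Figure D2:**
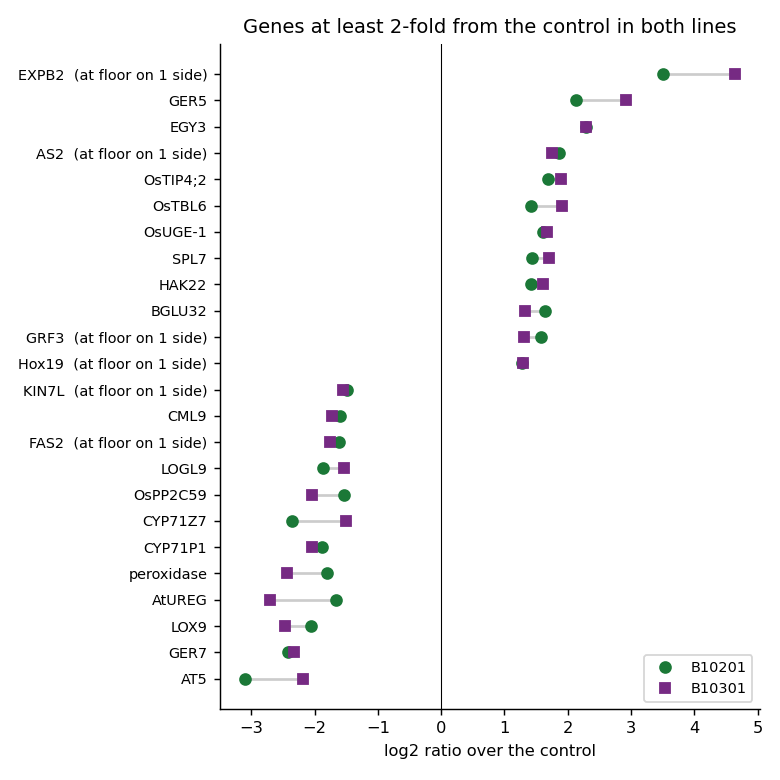
Log2 ratio over the control of the 24 readable genes ranked highest in each direction (12 higher, 12 lower) in B10201 (circles) and B10301 (squares); genes at the floor on at least 1 array are marked and give bounds. GER7, EGY3 and OsUGE-1 have nearly the same ratio in both lines, whereas EXPB2 and AT5 differ by more.

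Of 41 lists measured, 6 stood apart from random lists of equal size and signal in both lines, 1 higher and 5 lower. Both lines share 1 control array, so part of their agreement would arise without change, and this was not simulated for lists. The p-values of members come from the same ratios as the list medians. An unadjusted limma p under 0.05 was also frequent over all probe sets, as given above. Members that passed when adjusted over a list alone, here and in the closing section, therefore add no separate support for that list. Beyond the same bounds, 10 of the 41 lists differed between the lines. The cellulose list had a median log2 ratio of 0.71 in B10201 and 0.64 in B10301 (percentile 100 in each), with 15 of 19 members higher in both lines, 3 lower in both and 3 at least 2-fold higher in both. Unadjusted limma p was under 0.05 for 10 members, all higher; 9 passed when adjusted over the list alone and 0 over all probe sets. The synthases of the primary wall CESA1, CESA3 (0.78 and 1.11) and CESA6 (0.99 and 1.08) and those of the secondary wall CESA4, CESA7 (0.71 and 0.74) and CESA9 (1.16 and 0.49) were all on the higher side, with CSLE2 (-0.30 and -0.58) and CSLD2 (-0.19 and -0.31) lower.

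The chitinase and pathogenesis-related list had medians of -1.09 and -0.73 (percentiles 0.0 and 0.02). Of its 8 members 5 were lower in both lines, and PBZ1, Cht2, Cht11 (-1.38 and -1.02) and Cht6 (-1.16 and -0.93) passed when adjusted over the list alone, against 0 over all probe sets; the probe sets of Cht2 did not all share its sign and averaged -0.73, and Cht10 was higher (0.63 and 0.12). The diterpene phytoalexin list, of enzymes for antimicrobial compounds, had medians of -0.44 and -0.60 (percentiles 1.63 and 0.23) over 10 members, 7 lower in both lines. CPS2, a copalyl diphosphate synthase, was lower at -1.28 ± 0.03 (SD, n = 2 lines) and was the 1 member past the threshold adjusted over the list alone, with 0 over all probe sets; CPS4 (-1.53 and -1.01), CYP99A3 (-0.98 and -1.29) and CYP99A2 (-0.92 and -1.33) were also lower, and CYP76M6 higher (1.09 and 0.91). The list of that name fixed from descriptions had 3 measured members, CYP99A2, CYP99A3 and CYP76M6, all of them also on the longer list. Its medians of -0.92 and -1.29 (percentiles 1.95 and 0.73) are the values of CYP99A2 in B10201 and CYP99A3 in B10301. It therefore adds no separate support. The longer list no longer stood apart without a floor, as deposited or with the displaced values moved.

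Metal transporters for iron and zinc had medians of -0.42 and -0.36 (percentiles 0.02 and 0.05), with 18 of 25 members lower in both lines, 0 past the threshold adjusted over the list alone and 0 over all probe sets, and 7 lower with 2 higher at an unadjusted p under 0.05. OsZIP2 (-0.90 and -1.16), OsYSL13 (-1.01 and -0.83) and OsZIP5 (-1.38 and -0.75) were lower, and the vacuolar iron transporter OsVIT1 (0.52 and 0.62) higher. Cytochromes P450 had medians of -0.48 and -0.39 (percentiles 0.58 and 1.98) over 13 members, 6 lower and 4 higher in both lines, which include CYP99A2, CYP99A3 and CYP76M6 of the phytoalexin list; 1 passed when adjusted over the list alone and 0 over all probe sets. The P450 list no longer stood apart with quantile normalization, a floor at the 25th percentile, no floor or values as deposited, and the metal list without a floor.

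Ribosomal proteins had small medians of -0.14 and -0.23 (percentiles 0.46 and 0.0), with 19 of 25 members lower in both lines, 0 past the threshold adjusted over the list alone and 0 over all probe sets. The symbol pattern also took in RPP13-1, RPP16 and RPP17, symbols of phloem proteins, and without them the medians were -0.15 and -0.22 (percentiles 0.34 and 0.06). RPL18 (0.46 and 0.43), RPL27 (0.50 and 0.55) and rpl5 (0.51 and 0.74) were higher. Among members of the full list with an unadjusted limma p under 0.05, as many were higher as lower. Of genes on lists written for tissues that a leaf sample should lack, most lay below the floor. Measured were 2 of 9 on the seed storage list, 1 of 3 on the root list and 4 of 13 floral MADS-box genes. Some had high log2 signals in the control, with MADS16 at 10.30 and the seed storage gene GLUA-2 at 10.13, while MADS4 was at 6.74. NIP2-2 (x_at), taken in by the root symbol pattern, was at 13.55. Whether NIP2-2 is confined to roots was not tested, so its signal says nothing about root tissue. These lists therefore cannot settle whether the samples held leaf alone. Meristem and young-leaf genes had medians of -0.19 and -0.14 over 9 members, within the random lists (percentiles 22.0 and 26.1).

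**Figure D3:**
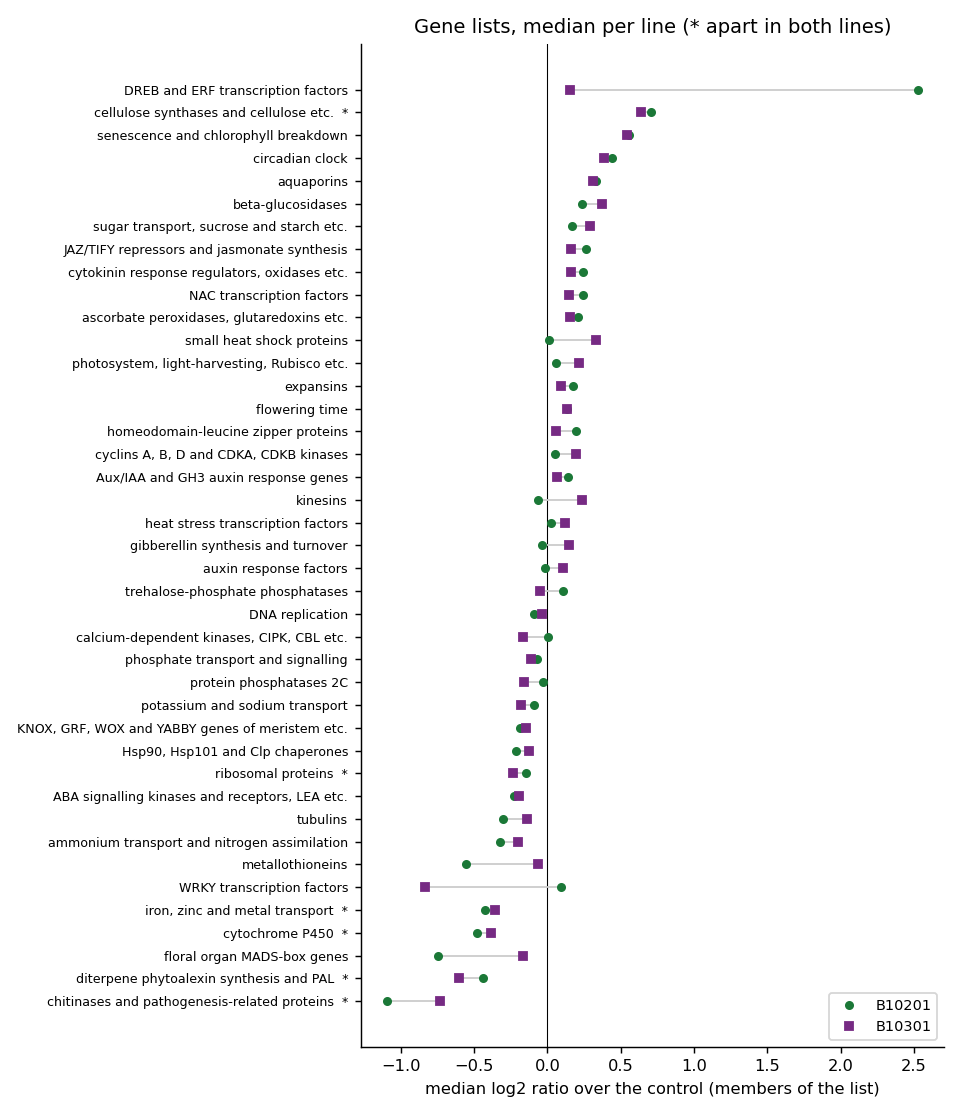
Median log2 ratio over the control of the measured members of each of 41 gene lists in B10201 (circles) and B10301 (squares), sorted by the mean of both; asterisks mark the 6 lists apart from 10000 matched random lists in both lines. Cellulose synthases lie at 0.71 and 0.64 and chitinases at -1.09 and -0.73, and the DREB list is high in B10201 alone.

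No gene of the annotation used here carried the symbol or synonym EBS, so the transgene's own level was not analysed here. The plan named Hsp70 genes of chromosome 5 to stand in its place, but members were sought here by symbol, whatever their chromosome. Hsp70 genes known by locus number alone could not be recognised. The only one found by symbol among the measured genes was BIP1, the chaperone of the endoplasmic reticulum. It was lower at -0.80 ± 0.05 (SD, n = 2 lines), from the high control signal of 14.48 on the log2 scale. The other 6 genes that the pattern matched, such as bip115 and bip130, carry a symbol used for proteins that interact with the receptor kinase BRI1, so no median is given for the family. Neither small heat shock proteins (0.01 and 0.34) nor heat stress transcription factors (0.02 and 0.12) stood apart.

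In B10201 alone, single genes of cold, jasmonate and calcium signalling were far above the other 2 arrays. DREB1G and DREB1A, transcription factors of the cold response, had log2 ratios over the control of 5.41 and 4.26 in B10201 against -0.11 and 0.00 in B10301; DREB1A was at the floor in the control and in B10301, so its difference of at least 19.2-fold is a bound. DREB2A was instead higher in B10301 (0.83) than in B10201 (0.26). JAZ13, a repressor of jasmonate signalling, was at 3.97 against -0.30, the calmodulin-like CML31 at 2.78 against -0.48, and OsSAP17, of a family of stress-associated zinc finger proteins, at 3.08 against -0.08. Loci with the largest such differences were LOC4325662 (x_at, 5.51 against 0.00, with its other probe set disagreeing in sign), LOC4325751, LOC4326920 and LOC4350213. In the other direction LOC4342395 was at -6.78 in B10201 and -1.10 in B10301, the metallothionein MT1B at -2.14 and 0.25, and LAC4, a laccase symbol, was 2.30-fold above the control in B10201 and 9.86-fold in B10301. LOC4343812, LOC4332506 and LOC4334399 completed that ranking by locus, and RIBA3, IAA30 and PXG that by symbol.

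Between the lines, 1372 probe sets differed at least 2-fold, 553 higher and 819 lower in B10301. From the control, 2496 probe sets differed in B10201 (1211 higher, 1285 lower) and 2339 in B10301 (1085 higher, 1254 lower). Of the 41 lists, 10 differed between the lines beyond the same bounds. DREB factors (median 2.53 in B10201 and 0.15 in B10301, 4 members), WRKY factors of the defence response (0.09 and -0.84, 6 members), jasmonate genes (0.26 and 0.16), calcium signalling genes (0.01 and -0.17, 56 members), protein phosphatases 2C, flowering genes and ribosomal proteins lay lower in B10301, and photosynthesis genes (0.06 and 0.22), tubulins and floral MADS-box genes higher. The WRKY members included OsWRKY71 (2.19 and -0.53) and OsWRKY76 (-0.91 and -1.99). The jasmonate and WRKY lists differed in this way in each of 8 other settings, and the ribosomal list in 7. The phosphatase, calcium (percentile of the difference 6.09 without a floor), DREB (11.2 without a floor) and photosynthesis lists (89.1 with quantile normalization) did in 6. Tubulins (82.1 with the displaced values moved) and floral MADS-box genes (51.7 without a floor) did in 4, and flowering genes (14.9 with a floor at the 75th percentile) in 3. With 1 array per line, these differences have no replicate check.

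Set against the other arrays in turn, the control stood furthest apart. It was at least 2-fold from both lines at 1243 probe sets, B10201 from both others at 586 (375 higher, 211 lower) and B10301 at 379. With all values as deposited B10301 stood furthest apart instead, at 3392 probe sets against 1408 for the control. Log2 signals correlated at 0.951 between the control and B10201, 0.955 between the control and B10301 and 0.974 between the lines, with median absolute differences of 0.35, 0.34 and 0.22.

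The lines' log2 ratios correlated across probe sets with a Pearson r of 0.724 and a Spearman rho of 0.681, with a covariance of 0.35. Unchanged lines simulated with 1 shared control gave a median r of 0.502 (0.484 to 0.528) and a covariance of 0.143 (0.132 to 0.153), so the covariance exceeded the simulated one by 0.207. The same simulations put 514.5 probe sets (446 to 574) at 2-fold in both lines, against 1243 observed. By direction they put 174 higher and 338.5 lower, against 546 and 697, so a surplus of lower probe sets also arose without change. Probe sets are not independent replicates, and with 1 control array part of the excess may come from that array.

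Genes set apart from the control were not spread evenly over the chromosomes of assembly ASM3414082v1. On chromosome 11, 66 of 509 measured genes (12.97%) were at least 2-fold from the control in both lines, 27 higher and 39 lower, against 4.70% over all chromosomes, and 44 of 593 (7.42%) on chromosome 12. Of the 90 genes at least 4-fold from the control in both lines, 20 lay on chromosome 11, 15 on chromosome 5 and 13 on chromosome 12. LOC4339438 and LOC4339505 were among 8 such genes, 7 of them higher, within 100 consecutive measured genes of chromosome 5; the densest such window held 4.33 on average and up to 8 after shuffling. LOC4352807, LOC9266439, LOC4352102, LOC4352036 and LOC9270774 all lay on chromosome 12. On chromosome 7, LOC4342229, LOC4342234, LOC4342242 and LOC4342251, all higher, lay at places 33, 35, 37 and 43 of 941 measured genes. Counted in a window of 100 genes, that group of 4 was below the shuffled mean of the densest window. This grouping was examined after the data were seen.

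**Figure D4:**
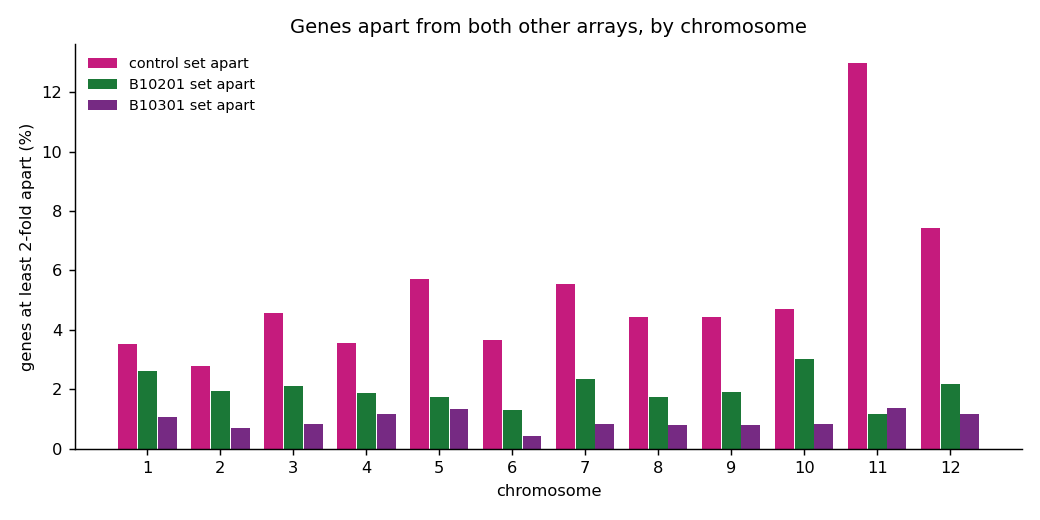
Share of measured genes (percent) on each chromosome of assembly ASM3414082v1 that were at least 2-fold from both other arrays, with each of the 3 arrays set apart in turn. For the control the share reaches 12.97% on chromosome 11 against 4.70% over all chromosomes, while those for B10201 and B10301 stay at or below 3.02%.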

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

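The treatments of the displaced stretches, limma on values not raised to the floor, averaged probe sets for named genes and the ribosomal list without RPP symbols were tests chosen only after the results were seen. The floor moved the counts most, since a lower floor keeps more dim probe sets and a higher one fewer. With floors at the 25th percentile, at the 75th percentile and without a floor, 5376, 402 and 9635 probe sets were at least 2-fold from the control in both lines (1243 as reported), 11027, 692 and 18349 in B10201 (2496), 11085, 605 and 18427 in B10301 (2339), and 10053, 196 and 17262 between the lines (1372). In the same order the correlation of the lines' ratios was 0.549, 0.805 and 0.534 (0.724), and for the array set apart the control's count was 1.14, 3.41 and 1.1 times that of the higher line (2.12 times). The count in both lines was 559 with 1 probe set per gene, for which fewer were tested, 3516 at 1.5-fold and 374 at 3-fold by construction, and 2339 to 2496 with 1 line left out, for which only 1 line had to differ. Quantile normalization, centring and leaving out x_at and s_at probe sets (1204, 1225 and 953) kept it within 1.5 times.

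limma called 0 probe sets as reported, 22 with centred arrays, 119 without a floor, 2 with 1 probe set per gene, 45 with robust moderation, 10 at a threshold of 0.1 and 85 with values not raised to the floor; the cause was not tested, except that a threshold of 0.1 admits more. All values as deposited gave 5528 probe sets in B10301, 4556 between the lines and a correlation of 0.317, and the comparison of arrays reversed, with the control's count 0.42 times that of B10301. These values include the displaced stretches by construction; with those values moved by 1 place the counts were 2627 and 1502, the correlation 0.724 and the ratio of counts again above 1 (1391 for the control against 657 for B10201). The number of gene lists apart was 6 as reported and 11 to 13 with 1 line left out, since only 1 line then had to pass. The cellulose, ribosomal and chitinase lists stood apart in each of the 8 other settings of the lists; the P450 list no longer did in 4 of them, the phytoalexin list in 3 and the metal list in 1, while beta-glucosidases stood apart in 5, Hsp90 and Clp chaperones in 2 and aquaporins in 1; the cause was not tested. Of 157 named genes with 1 sign in both lines, NIP2-2 changed sign with quantile normalization and OsSWEET1a with averaged probe sets, and only 93 had a value with a floor at the 75th percentile. Over all settings 1283 of the values of single genes and of the 6 lists apart from the control stayed within their spread or side of the bounds, 89 moved and 8 no longer stood apart.

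No paired analysis was possible because the control has 1 array. Signal over background limits what was seen: 26637 of 49409 probe sets had a mean at or below the floor.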

Other observations

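The tests of displaced values, of gene order at 4-fold, of the control pool and of the genes high in B10201 were chosen only after the results were seen, while those of scaling other than that of B10201, dim signals, neighbouring genes in B10301 and the shared control were written before their results were seen. Several other gene groups stood on 1 side in both lines without passing the bounds for lists in both. Chlorophyll breakdown genes were higher, with the chlorophyll b reductase NYC1 at a mean log2 ratio of 0.55 ± 0.01 (SD, n = 2 lines) and the stay-green gene SGR (s_at) at 0.95 ± 0.08; the 3-member list had medians of 0.56 and 0.54 (percentiles 96.8 and 95.9), with 2 members past the limma threshold adjusted over the list alone and 0 over all probe sets. Sugar and starch genes, whose symbol pattern also took in the fatty acid desaturase OsSSI2, had medians of 0.17 and 0.29 (percentiles 95.0 and 99.5), among them AGPS2, a subunit of the enzyme that makes ADP-glucose for starch (0.59 and 0.57), while the sucrose synthase OsSUS4 was lower (-0.77 and -0.48) and the sugar transporter OsSWEET1a (0.68 and 0.79) changed sign when its probe sets were averaged. Aquaporins leaned higher in 11 of 14 members (0.33 and 0.31; percentiles 96.3 and 91.1; past the bounds in 1 of 8 other settings), among them OsTIP2;2 (x_at, 0.89 and 0.64) and OsPIP2;2 (0.64 and 0.52). Of 17 beta-glucosidases (medians 0.24 and 0.37; percentiles 96.8 and 99.5), whose list passed the bounds as higher in 5 of 8 other settings, 4 passed when adjusted over the list alone and 0 over all probe sets, with BGLU3 (1.16 and 0.99) higher and BGLU14 (-1.10 and -1.25) lower.

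Lower in both lines were the ammonium transporter AMT3-2 (x_at, -1.26 and -1.01), the phosphate sensor OsSPX2 (-1.02 and -1.16) and the metallothionein MT-1 (-1.36 and -1.39). Of the 6 metallothioneins, 3 were lower and 2 higher in both lines, with MT-2 (s_at) at 0.46 and 0.58. The metallothionein list had medians of -0.55 in B10201 and -0.06 in B10301 (percentiles 0.31 and 18.3). Single genes of other lists were lower too, with the repressor-type factor OsWRKY62 at -1.64 and -1.44, the lipoxygenase LOX2.1 at -1.29 and -1.98 and the calmodulin-like CML4 at -1.23 and -1.15 (mean -0.78 with its probe sets averaged), while the WRKY, jasmonate and calcium lists that hold them had medians of 0.09, 0.26 and 0.01 in B10201 and -0.84, 0.16 and -0.17 in B10301 (percentiles 77.4, 99.0 and 69.5, and 0.05, 92.3 and 0.94). The cytokinin oxidase CKX4 was higher (0.99 and 0.87), as was the photosystem II protein PSB28 (0.73 and 0.80), but the photosynthesis list as a whole lay within the random lists. None of these genes passed limma's adjustment over all probe sets.

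In the values as deposited, B10301 stood furthest from the other arrays. Scaling did not account for it, since with quantile normalization 3398 probe sets were still set apart in B10301 against 1372 for the control. Dim signals did not either, with 1428 against 422 at a floor at the 75th percentile, nor did differing stretches of genome in that line, as neighbouring genes were set apart together 1.05 times as often as after shuffling. With the values of the stretches moved back by 1 place, and so with those probe sets kept, the count for B10301 was 409, below the control's 1391, so displacement of table values is a likely cause of the pattern.

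The control differed from both lines together at 1243 probe sets, more than the highest of 100 simulations with a shared control (574). The simulated control varied like the lines, so this argues against chance only if the real control array varied no more than they did. A control array that was off in itself stays open. With quantile normalization the control's count was 2.02 times that of B10201, which argues against intensity-dependent scaling as the whole cause. Without a floor the counts were closer, at 9635 for the control against 8751 for B10301. Genes at least 4-fold from the control in both lines lay near each other: 82 pairs were 6 to 50 places apart on a chromosome, 2.76 times the mean after shuffling gene order (29.7; highest of 1000 shuffles 52), against 1.29 times for the genes at 2-fold, and 31 of the pairs held 1 higher and 1 lower gene. With the displaced values moved back the ratio was 2.76 as well, over 112 genes. A candidate explanation of part of the differences is a hypothesis from the same data. The plants of both lines and those of the control may differ in stretches of their genome. Differing alleles or absent genes would then add to the measured differences. The pairs were counted over all chromosomes together, so they do not place such stretches on particular chromosomes. Gene families that cluster along chromosomes would also lie together and were not tested. The state of the control plants, of which there was 1 pool, and an effect of OsEBS, which differs between the same samples, cannot be told apart from each other and stay open.

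In B10201, 54 genes were at least 4-fold from both other arrays, against 3 in B10301, with DREB1G, DREB1A, JAZ13, JAZ10 (s_at, 4.10 in B10201 and 1.18 in B10301) and CML31 among the named ones. Scaling of the array did not account for this, as quantile normalization gave 57 such genes against 3 for B10301, and the genes did not lie together over longer stretches of chromosome (pairs 6 to 50 places apart 1.05 times the shuffled mean). Adjacent pairs numbered 1 at 4-fold (highest of the shuffles 3) but 13 at 2-fold, against a shuffled mean of 5.07 (highest 12) in 1 set of shuffles and 4.91 (highest 17) in another, so small groups of adjacent genes stay open for the wider set. The 4 stress signalling lists examined (DREB, jasmonate, calcium, WRKY) lay lower in B10301 than in B10201, but they were picked after their values were seen, so this tests nothing, and the ABA, small heat shock, heat stress factor and redox lists did not lie lower (percentiles of the difference 68.9, 86.5, 70.1 and 55.6). A short-lived stress response of the B10201 plants at harvest cannot be told apart from a lasting effect in that line, because each line has 1 array.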
